A study of Mus musculus with 15 samples.

How the data were processed

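RNA was measured in 15 samples labelled as brain hemisphere from mice aged 12 months, 7 with the PLP-α-synuclein transgene (TG) and 8 without it (WT). Per the labels, each library was made from 250 ng of total RNA with a stranded kit that removes ribosomal RNA, and was sequenced as paired reads of 100 bp. The deposited values are whole-number counts of reads per gene. Per the submitters' processing notes, reads were aligned with STAR 2.7.5b to GRCm38 and counted with featureCounts from Subread. Whether the counting used strand, counted fragments or single reads, or kept reads with several matches was not given in the sources used here.

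The table held 27179 gene IDs for 15 libraries, and each column was matched to its sample by the library number in the sample title. NCBI gene IDs were matched to RefSeq names and positions on GRCm38.p6 for 25275 IDs, and a further 18 were named through GENCODE. No symbol was found for 1886 IDs, which held 0.836% of all counts. Genes of the mitochondrial genome were not analysed here. A count was above 0 in at least 1 library for all but 3470 IDs. Library totals ran from 15170772 to 35850998 counts with a median of 17635366. No pair of libraries agreed within sampling noise, the lowest chi-square per gene being 6.79. The limit that 3 counts allow was 0.0837 CPM in the deepest library and 0.198 CPM in the shallowest, and such limits cover counting error alone.

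Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 4 genotype-by-sex groups, which left 17151 genes, 551 of them without a symbol. Library sizes were scaled with TMM, and the quasi-likelihood F test was run with robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. Genotype was tested in all 15 libraries with sex as a covariate, and sex with genotype as a covariate. Genotype within females, within males and the genotype-by-sex interaction were contrasts in a model of 4 group means. CPM values use TMM-scaled library sizes and are given as mean ± SD over libraries. Fold changes are log2 values ± SE from the fit.

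These designs, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. The rule named Sncb, Sncg, Y-linked and X escape genes and C57BL/6 substrain genes in all cases. It then named called genes with a mean of at least 1 CPM by size of the fold change, up to 12 per direction for genotype and 6 per direction within each sex. Where too few genes passed, the 3 with the smallest p were named and are said not to pass. Predicted genes, pseudogenes and IDs without a symbol were counted and not named, apart from Gm2223, Gm15446 and Gm3435. Gm2223 was the only gene called between the sexes outside the Y-linked and X escape genes. Of each gene list described, members called, or else up to 2 with the smallest p, were named. Lists described are those past the threshold for genotype with or without the region term introduced here, a restriction set after the results were seen. Gm15446, Gm3435 and the 9 library markers Hoxa5, Slc6a5, Neurod6, Gabra6, Cbln3, Mbp, Eomes, Omp and Th were chosen after their values were seen. Results for some genes that these rules named, and the tests that needed them, are not reported here.

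Of 39 fixed gene lists, 4 were read gene by gene, namely the list with Sncb and Sncg, the Y-linked genes, the X escape genes and the substrain genes. The other lists cover brain cell types, brain regions, immune and stress responses and metabolism, and the 33 with at least 5 tested members were tested with camera from limma 3.58.1 at its preset correlation of 0.01. The list of pituitary genes had 4 tested members and a median log2 fold change of -0.33 between TG and WT, with no test. Each list was tested again with camera's estimated correlation and with fry.

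Libraries within a group differed in brain region markers, so 4 library classes were formed after the data were seen, by Ward clustering on the fixed region lists alone. These were the lists of excitatory neurons, striatal projection neurons, cerebellum, hindbrain and hypothalamus. Since they formed the classes, the loss of a call for one of them with the region term is no independent evidence on region content. A region term for these classes, leaving out 5 libraries, and both together were added as alternatives. Genotype was not used to form the classes. The other settings tried were DESeq2 1.42.0, limma-voom, 1 surrogate variable from sva 3.50.0, other size factors, other filters, non-robust fits, the replicate number as a block, each sex alone, no sex covariate, a minimum fold change, leaving out the most abundant genes, and each library left out in turn.

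The fit was tested on simulated counts for 17151 genes with 50 genes changed at each of 4 sizes. For TG versus WT, 58% of the 2-fold changes and 96% of the 4-fold changes were recovered, with 5 unchanged genes called. These shares were 80% and 98% with the region term, with 15 unchanged genes called. At 4-fold, recovery was 64% within females, 76% within males, 52% for the interaction and 84% for sex. A simulated list moved 1.5-fold was called by camera and by fry, with 0 of the other lists called. Simulated genes were drawn independently of each other. The simulations therefore cannot show how many false calls of genes or lists arise where genes vary together between libraries.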

Results

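The series measured gene expression in samples labelled as brain hemisphere, from mice that overexpress human α-synuclein under the PLP promoter. This promoter is active in oligodendrocytes, the myelin-forming cells of the brain. The line is a model of multiple system atrophy, in which α-synuclein accumulates in oligodendrocytes. Homozygous transgenic animals (TG) were compared with non-transgenic animals (WT) of a C57BL/6 background in both sexes. There were 4 WT female, 4 TG female, 4 WT male and 3 TG male samples, all from mice 12 months old. The labels describe mice and give each library its own sample, so p-values measure the spread between these samples. Each group also had its own prefix in the sample titles, so anything shared within a group, such as litter or cage, cannot be separated from it.

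Library totals were 16077773, 21401727, 24348166 and 17453632 counts for WT males 1 to 4. They were 15766779, 19956555, 35850998 and 17635049 counts for WT females 1 to 4. TG females 1 to 4 had 15170772, 19075810, 16495909 and 17519704 counts, and TG males 1, 3 and 4 had 17635366, 17870224 and 19451854. Expression is given as CPM, the count of a gene scaled to its library total after TMM adjustment.

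Libraries of the same group held markers of different brain regions. Hoxa5, a patterning gene of the hindbrain and spinal cord, lay at 69.3 to 121 CPM in 4 libraries (WT male 3, WT female 3, TG females 1 and 4) and at no more than 1.97 CPM in the other 11. Slc6a5, the glycine transporter of brainstem neurons, lay at 61.9 to 103 CPM in the same 4. Mbp, a main myelin protein, lay at 10598 to 13230 CPM there against 937 to 3258 CPM elsewhere. Gabra6, a receptor subunit of cerebellar granule neurons, lay at 701 CPM in TG female 3 and at no more than 1.19 CPM in every other library. Neurod6, a transcription factor of excitatory cortical neurons, lay at 131 to 171 CPM in WT male 4, WT female 2 and TG male 4, and at no more than 55.8 CPM elsewhere. In the remaining 7 libraries Omp, a marker of olfactory sensory axons, lay at 42.2 to 159 CPM, against no more than 2.71 CPM in the other 8. These 4 library classes explained 98.5% of the first principal component, which held 49.1% of the variance, while the 4 genotype-by-sex groups explained 28.6% of it. No TG male library was among the 4 with hindbrain markers, and the 1 library with cerebellum markers was TG.

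**Figure D1:**
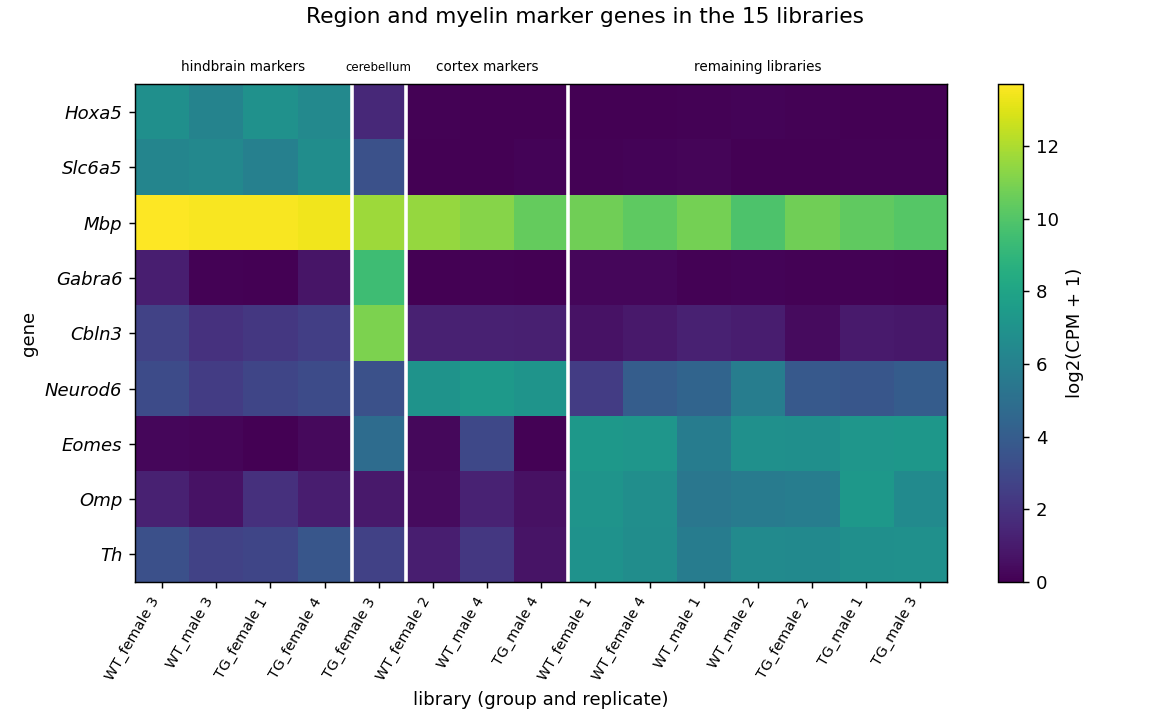
Expression of 9 marker genes (vertical axis) in each of the 15 libraries (horizontal axis, group and replicate), coloured by log2(CPM + 1). White lines part the libraries with hindbrain markers (4), cerebellum markers (1) and cortex markers (3) from the remaining 7, and Hoxa5 reached 69.3 to 121 CPM in the first 4 alone.

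Sncb and Sncg, which encode β-synuclein and γ-synuclein, had log2 differences of -0.06 ± 0.19 and -0.82 ± 1.67 between TG and WT, neither past the threshold.

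Between TG and WT, over both sexes, 19 genes passed the threshold, 7 higher and 12 lower in TG. The genes that fell included Mcm6, a subunit of the replicative DNA helicase, Nav1, a microtubule-associated neuron navigator, Tnnt2, the cardiac troponin T, and Aldh7a1, an aldehyde dehydrogenase of lysine breakdown. Several γ-protocadherins, cell-surface adhesion proteins of neurons encoded in 1 gene cluster, moved in both directions: Pcdhga4, Pcdhgb4 and Pcdhga8 rose and Pcdhga11 fell. None of the 19 was a member of a tested gene list.

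Mcm6 (chromosome 1, 128331575 to 128359705) lay at 0.700 ± 0.245 CPM in TG (SD, n = 7) and 3.48 ± 0.780 CPM in WT (SD, n = 8). Its log2 value fell by 2.32 ± 0.25, with an adjusted p of 9.83e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nav1 (chromosome 1, 135434580 to 135688350) lay at 77.5 to 151 CPM in TG and 208 to 320 CPM in WT and fell by 1.07 ± 0.14, with an adjusted p of 0.00426 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tnnt2 (chromosome 1, 135836315 to 135852268) was at 0 to 0.220 CPM in TG, near the limit that 3 counts allow, and at 1.11 to 7.05 CPM in WT. Aldh7a1 (chromosome 18, 56524722 to 56572991) fell by 0.71 ± 0.08, from 39.3 ± 2.97 to 24.1 ± 2.52 CPM. Tcte3 and Ermard, overlapping neighbours on chromosome 17 (Tcte3 at 15027154 to 15041559, Ermard at 15041551 to 15090045), fell by 1.61 ± 0.20 and 0.81 ± 0.11. For Tnnt2, Aldh7a1, Tcte3 and Ermard the adjusted p was 0.00295, 0.00121, 0.00347 and 0.00406 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

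Among the γ-protocadherins of chromosome 18, Pcdhga4 (37685237 to 37841870) rose by a log2 value of 1.05 ± 0.15, from 21.5 ± 4.81 to 44.2 ± 6.19 CPM. Pcdhgb4 rose by 0.83 ± 0.14 and Pcdhga8 by 0.73 ± 0.13, while Pcdhga11 fell by 1.38 ± 0.21. Their adjusted p was 0.00698, 0.0286, 0.0411 and 0.0171 in this order, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These genes share their 3' exons, so reads from the shared part may have been split between members, and the calls for Pcdhgb4, Pcdhga8 and Pcdhga11 held in 3, 5 and 10 of 15 fits with 1 library left out. Of the 19 genes, 8 were predicted genes, pseudogenes or had no symbol. The smallest adjusted p was that of Gm15446, a predicted gene (chromosome 5, 109933563 to 109941710), at 3.57e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gm15446 lay at 9.42 to 16.8 CPM in TG and 0.185 to 0.492 CPM in WT. Gm3435, on chromosome 17 beside Tcte3, fell by 1.42 ± 0.16.

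**Figure D2:**
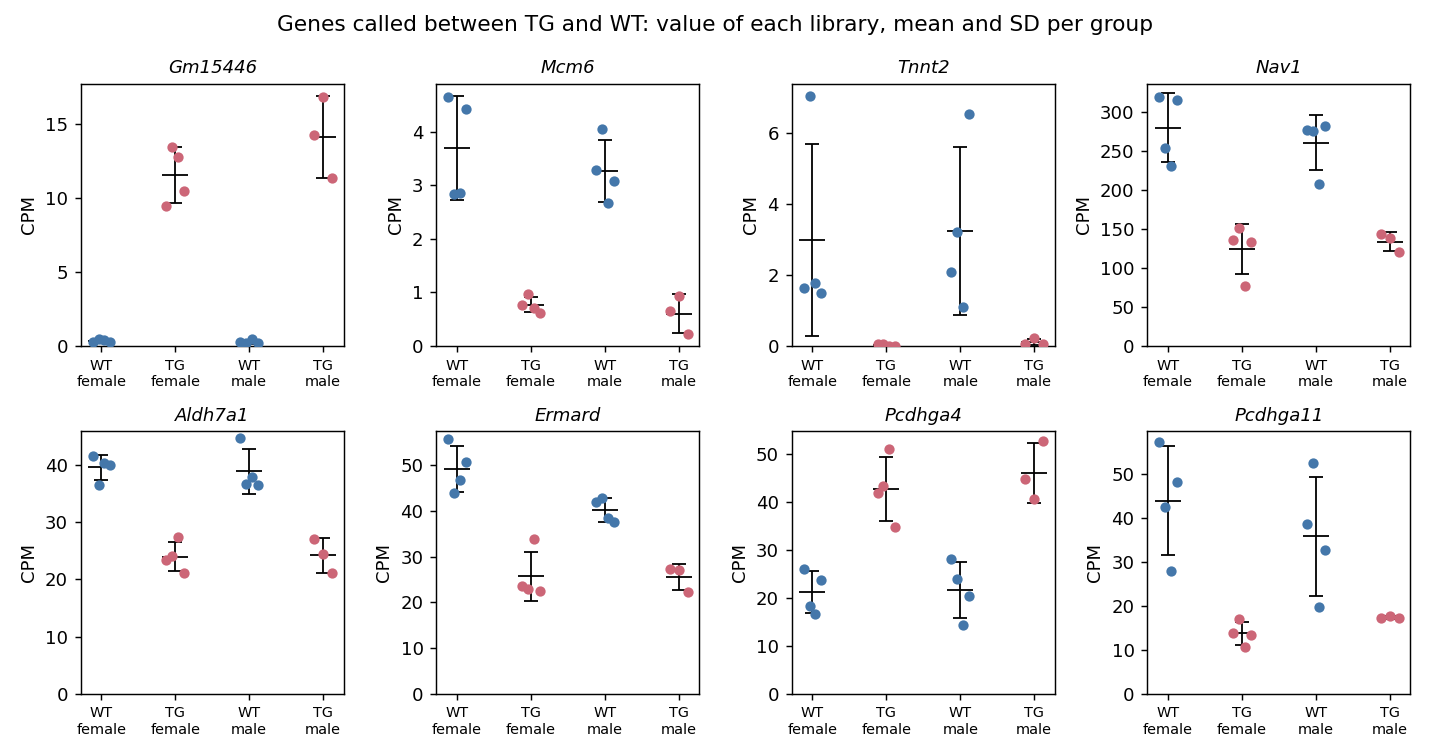
CPM (vertical axes) of 8 genes called between TG and WT, with 1 point per library in each of the 4 groups, WT in blue and TG in red, and lines at the mean and SD. Gm15446 lay above 9 CPM in all 7 TG libraries and under 0.5 CPM in all 8 WT libraries.

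With a term for the 4 library classes, chosen after seeing the data, 85 genes passed the threshold, 40 higher and 45 lower in TG, and they included all 19. The class with cerebellum markers held TG female 3 alone, so that library added nothing to the genotype effect in this fit. The class with cortex markers held 1 TG library. The biological coefficient of variation was 43.1% without the term and 14.2% with it. Genes that rose in this fit included 7 more named protocadherins, among them Pcdhb8 and Pcdhb11 of the β cluster, and Aim2, a cytosolic DNA sensor. Another protocadherin newly called, Pcdhgb6 of the γ cluster, fell. Genes that fell included Gpr55, a lipid-sensing receptor, Cd59a, a complement inhibitor, and Klk6, a secreted protease of oligodendrocytes, and Anln, an actin-binding protein. Pcdhb8 rose by a log2 value of 1.28 ± 0.11 and Aim2 by 1.10 ± 0.15, while Gpr55 fell by 1.56 ± 0.18, Cd59a by 1.09 ± 0.12, Klk6 by 1.07 ± 0.19 and Anln by 0.95 ± 0.14. Their adjusted p in this order was 7.05e-05, 0.00352, 8.39e-04, 8.39e-04, 0.0256 and 0.00622 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without the 5 libraries with hindbrain or cerebellum markers, also chosen after seeing the data, 7 genes passed, 6 of them among the 19, and with both changes 41 passed, 17 of them among the 19 and 34 among the 85. Pcdhb8, Pcdhb11 and Gpr55 were among these 34, while Aim2, Cd59a, Klk6 and Anln did not pass there, and the difference of Klk6 ran from -2.24 to -0.09 over all settings.

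Without the region term the called genes lay on few chromosomes. Of the 16 with a position, 3 lay on chromosome 1, 5 on chromosome 17, 6 on chromosome 18, and 1 each on chromosomes 2 and 5. With the region term, 20 of the calls lay on chromosome 1, 10 on chromosome 17 and 27 on chromosome 18, the last being 5.99% of the 451 genes tested there. Of these 27, 21 lay in 1 locus at 36.7 to 37.8 Mb that holds the protocadherins. Chromosome 2 held 6 further calls, chromosome 5 held 4, chromosomes 11 and 13 held 3 each, and chromosomes 3, 7, 9, 10 and X held 1 or 2 each. The 81 calls with a position formed 43 loci, where neighbouring calls within 2 Mb were joined.

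**Figure D3:**
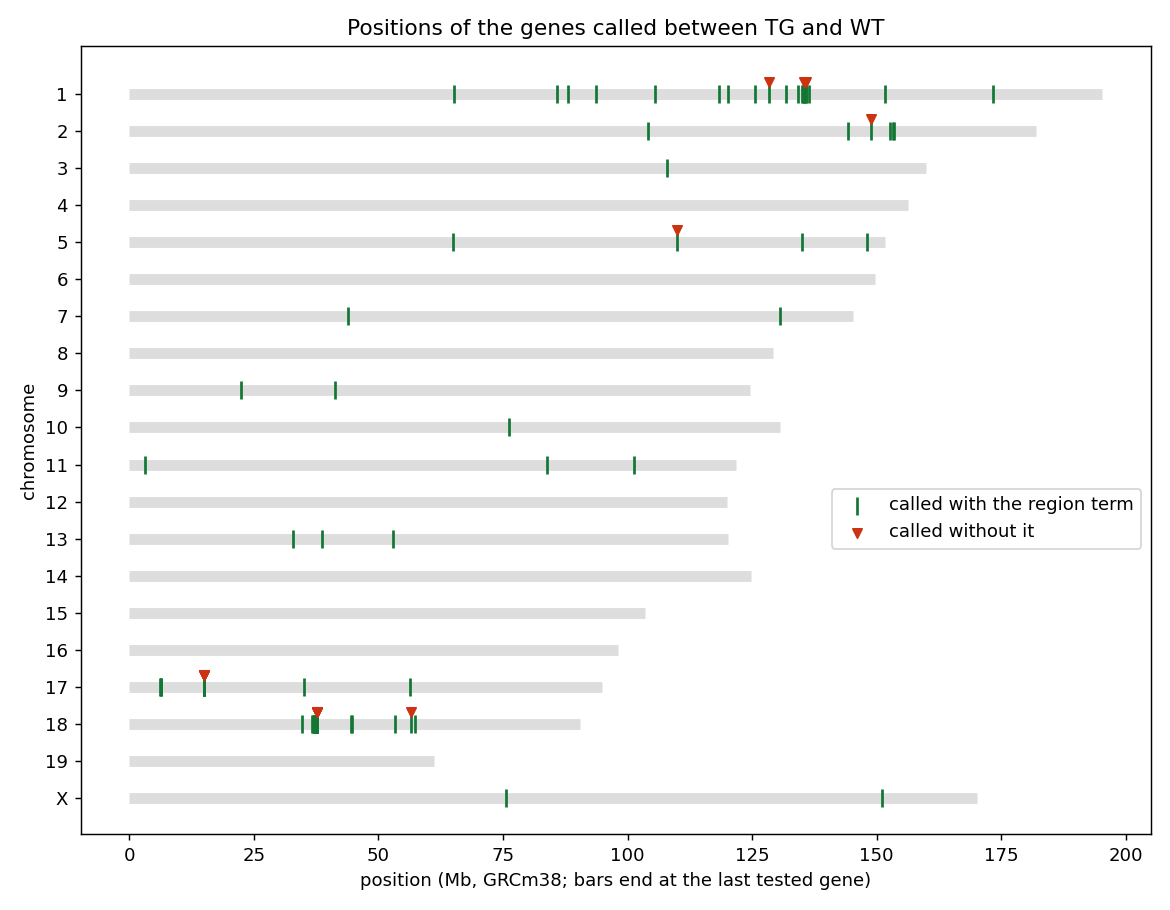
Positions in Mb on GRCm38 (horizontal axis) of the genes called between TG and WT on each chromosome (vertical axis), with green bars for calls with the region term and red triangles for calls without it. Chromosomes 1, 17 and 18 hold 20, 10 and 27 of the calls with the region term.

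Among the fixed gene lists, interferon response and antigen presentation genes lay higher in TG over all 15 libraries and cholesterol synthesis genes lower. Of 34 interferon response genes 33 had a positive log2 fold change, with a median of 0.52. Of 22 antigen presentation genes 19 were positive, with a median of 0.40, and of 23 cholesterol synthesis genes 2 were positive, with a median of -0.23. In camera their adjusted p was 1.52e-14, 6.07e-11 and 4.66e-07, and with an estimated correlation the adjusted p was 0.653, 0.467 and 0.819. No member of these lists passed the threshold over all genes or adjusted over the list alone. All 3 lists stayed past the threshold in camera with the region term, where 15 cholesterol synthesis genes were lower adjusted over the list alone, and in that fit the adjusted p with an estimated correlation was 0.758, 0.721 and 0.312. TG female 2 stood apart from the other TG females, with a mean log2 CPM of 4.11 for interferon response and 3.99 for antigen presentation genes against 2.37 to 2.69 and 3.13 to 3.59. Both lists stayed past the threshold in camera without that library, with an adjusted p of 2.92e-05 and 5.82e-06. Within females the interferon list did not pass in camera without it, with an adjusted p of 0.866, and the antigen presentation interaction did not either, with an adjusted p of 0.0696. The cholesterol list did not pass in females in camera without the region term. It passed there with the term, with an adjusted p in camera of 0.00234, while with an estimated correlation no list passed in that fit.

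By gene, H2-Q7, a nonclassical class I histocompatibility gene with near-identical copies, had a log2 difference of 1.20 ± 0.33, H2-Q6 one of 1.06 ± 0.35 and B2m, the class I light chain, one of 0.42 ± 0.18. Xaf1 and Irf9 of the interferon list had differences of 0.58 ± 0.25 and 0.39 ± 0.17. Lss, the lanosterol synthase of the cholesterol list, had a difference of -0.23 ± 0.08. The class means also differed: interferon response genes averaged a log2 CPM of 2.79 in the 7 remaining libraries and 1.62 in the 3 with cortex markers, and antigen presentation genes 3.39 with hindbrain markers and 2.50 with cortex markers. Cholesterol synthesis genes averaged 5.90 with hindbrain markers and 5.11 in the remaining 7. By library, interferon response genes averaged 2.94 to 4.11 in TG and 1.78 to 2.92 in WT among the remaining 7. With hindbrain markers they averaged 2.37 and 2.68 in TG and 2.61 and 3.15 in WT, and with cortex markers 1.56 in TG and 1.41 and 1.90 in WT. The interferon list was thus higher in TG among the remaining 7 and not in these 2 classes.

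Of 33 lists tested, 13 passed the threshold in camera, 8 upward and 5 downward, and 0 did so with an estimated correlation or in fry, where 2 and 0 lists had an unadjusted p under 0.05. The cerebellum list passed upward with a median of 1.23, and its mean log2 CPM was 7.86 in TG female 3 and 1.88 to 3.04 in the other classes. The glucocorticoid response (median 0.16), disease-associated microglia (0.08), disease-associated oligodendrocyte (0.17), reactive astrocyte (0.07) and cytosolic ribosomal protein (0.06) lists also passed upward. The lists of blood (-0.27), excitatory neurons (-0.46), striatal projection neurons (-0.22) and oligodendrocyte precursors (-0.10) passed downward. For these 10 lists, in the order given, the adjusted p in camera was 1.72e-04, 2.14e-04, 6.84e-04, 0.00599, 0.0156, 0.0248, 0.00135, 0.00687, 0.0194 and 0.0221. With an estimated correlation the adjusted p was 0.839, 0.467, 0.839, 0.705, 0.839, 0.839, 0.653, 0.839, 0.839 and 0.839. In camera with the region term the glucocorticoid, ribosomal protein and blood lists stayed past the threshold and the other 7 did not, and with an estimated correlation the adjusted p of these 3 was 0.721, 0.994 and 0.721. For those 7, the cerebellum, microglia, oligodendrocyte, astrocyte, excitatory, striatal and precursor lists, the adjusted p in camera was 0.840, 0.0607, 0.151, 0.130, 0.889, 0.889 and 0.0979 in that fit, where camera ranked cerebellum downward and excitatory neurons upward. The cerebellum, excitatory and striatal lists had helped form the library classes, so their loss was no independent test. With 1 library left out, the calls in camera without the term held in 8 of 15 fits for the striatal and ribosomal protein lists, 10 for the excitatory neuron and precursor lists, 12 for reactive astrocytes, 13 for the microglia and oligodendrocyte lists, 14 for blood and cerebellum and 15 for glucocorticoid response, and without WT male 1 the striatal list had an adjusted p in camera of 0.728. Excitatory neuron genes averaged a log2 CPM of 7.52 in the libraries with cortex markers and 4.20 in those with hindbrain markers, and striatal genes 5.10 in the remaining 7 and 3.84 with hindbrain markers. Disease-associated microglia, disease-associated oligodendrocyte and reactive astrocyte genes averaged 4.25, 5.66 and 3.08 with hindbrain markers and 3.08, 4.33 and 1.93 with cortex markers.

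Members of these lists did not pass the threshold over all genes without the region term, and adjusted over the list alone 3 blood genes were lower. Hba-a1 and Hba-a2, the α-globin genes, had log2 differences of -1.30 ± 0.47 and -1.32 ± 0.46. Cst7 and Lgals3bp, raised in activated microglia, had differences of 1.17 ± 0.54 and 0.72 ± 0.32. Of the reactive astrocyte list, Cd14 had a difference of 0.62 ± 0.23, while Ptgs2 ran against the list's direction at -1.64 ± 0.67. Cd14, beside the protocadherins on chromosome 18, was called with the region term at 0.57 ± 0.09, with an adjusted p of 0.0132 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Klk6 of the oligodendrocyte list was also called in that fit, but it fell, against the list's direction. Plin4 and Sult1a1, shared by the glucocorticoid and oligodendrocyte lists, had differences of 1.07 ± 0.52 and 0.40 ± 0.15. Gabra6 and Gdf10 of the cerebellum list had differences of 7.93 ± 2.63 and 1.92 ± 0.87, and TG female 3 lay at 701 CPM for Gabra6 and 251 CPM for Gdf10. Pdgfra and Cspg4, surface proteins of oligodendrocyte precursors, had differences of -0.22 ± 0.15 and -0.34 ± 0.16. Fezf2, Foxp2, Foxp1 and Gng7 of the neuron lists had differences of -2.61 ± 1.59, -0.54 ± 0.32, -0.29 ± 0.42 and -0.46 ± 0.54, and Rpl18 and Rps2 of 0.15 ± 0.11 and -0.12 ± 0.09.

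The myelin list did not pass without the region term, with a median of -0.40 and an adjusted p in camera of 0.176. With the region term it passed downward, with a median of -0.25 and 25 of 30 members negative, an adjusted p in camera of 2.84e-07 and an adjusted p of 0.721 with an estimated correlation. Hapln2, a protein of the node of Ranvier, and Car2, the oligodendrocyte carbonic anhydrase, had differences of -0.71 ± 0.16 and -0.32 ± 0.10 in that fit. Myelin genes averaged a log2 CPM of 7.82 with hindbrain markers and 5.38 in the remaining 7. By library, they averaged 5.11 to 5.72 in TG and 4.89 to 5.71 in WT among the remaining 7. With hindbrain markers they averaged 7.80 and 7.62 in TG and 7.90 and 7.95 in WT. With cortex markers they averaged 5.27 in TG and 5.92 and 6.23 in WT. The myelin list was thus lower in TG with hindbrain or cortex markers and not among the remaining 7. The circadian clock list also passed with the region term alone, with a median of 0.06, an adjusted p in camera of 0.0131 and an adjusted p of 0.721 with an estimated correlation. Cry1 and Bhlhe41 of that list had differences of 0.46 ± 0.22 and 0.22 ± 0.14 without the term.

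The lists that did not pass in either fit had these adjusted p values in camera without the region term: endothelium 0.0533, choroid plexus and ependyma 0.0818, immediate early 0.0951, homeostatic microglia 0.111, synaptic vesicle and release 0.179, nuclear oxidative phosphorylation 0.206, complement 0.206 and astrocyte 0.340. In camera the adjusted p was 0.344 for hypothalamus, 0.3995 for dopaminergic neurons, 0.3995 for disease risk genes, 0.508 for lysosome and autophagy, 0.555 for inhibitory neurons and 0.555 for mural cells. It was 0.576 for heat shock, 0.789 for lymphocytes and 0.907 for meninges in camera. The hindbrain list had a median of -1.19 while camera ranked it upward, with an adjusted p of 0.3995, and the meninges list had a median of -0.04 while camera ranked it upward.

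**Figure D4:**
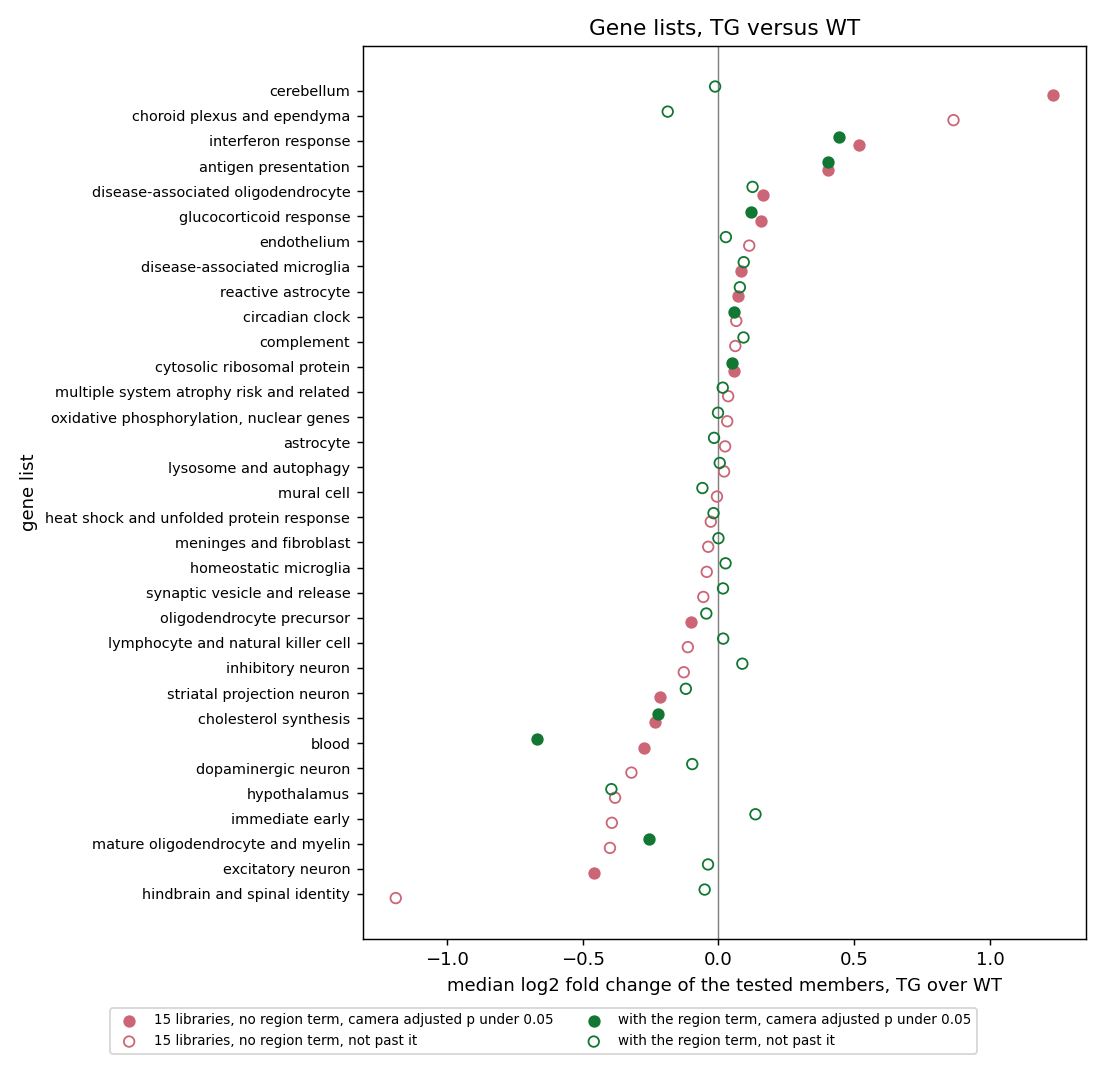
Median log2 fold change of TG over WT (horizontal axis) for the tested members of each gene list (vertical axis), red without and green with the region term, filled where camera's adjusted p was under 0.05. Interferon response stood at 0.52 and 0.44 and cholesterol synthesis at -0.23 and -0.22.

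Of the C57BL/6 substrain genes, Nnt, Wdfy1, Entpd4, Gabra2, Ide and Fgfbp3 did not pass the threshold between TG and WT. Their log2 differences were -0.07 ± 0.11, -0.02 ± 0.09, -0.07 ± 0.16, -0.27 ± 0.21, 0.06 ± 0.08 and -0.20 ± 0.17. Mmrn1 lay at 0.0256 CPM in WT and 0.0572 CPM in TG, under the limit that 3 counts allow, and was not tested.

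In females, TG and WT differed in 8 genes, 1 higher and 7 lower in TG, and all 8 were among the 19. Mcm6, Tnnt2, Ermard and Aldh7a1 fell. Mcm6 fell by a log2 value of 2.25 ± 0.35, Ermard by 0.94 ± 0.14 and Aldh7a1 by 0.73 ± 0.11, each with an adjusted p of 0.0456 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tnnt2 had the same adjusted p of 0.0456 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other 4 genes were predicted genes, pseudogenes or had no symbol, including Gm15446, which rose by 4.97 ± 0.31. Fitted to the 8 female libraries alone, 1 gene passed, and without TG female 1, which has hindbrain markers, 1 gene passed.

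In camera 20 lists passed in females, 17 upward and 3 downward, and 0 did so with an estimated correlation or in fry. Antigen presentation genes had a median log2 difference of 0.56 and 19 of 22 positive members, with an adjusted p in camera of 6.59e-11 and an adjusted p of 0.430 with an estimated correlation. Disease-associated microglia genes had a median of 0.36 and 27 of 29 positive members, with an adjusted p in camera of 1.71e-08 and an adjusted p of 0.564 with an estimated correlation. The cerebellum, choroid plexus, hindbrain and hypothalamus lists also passed upward, with medians of 2.29, 1.92, 0.93 and 1.17, and excitatory neuron and immediate early genes downward, with medians of -1.08 and -1.18. For these 6 lists the adjusted p in camera was 8.57e-07, 1.31e-05, 4.58e-05, 0.0127, 3.18e-05 and 1.51e-05, and the adjusted p was between 0.564 and 0.618 with an estimated correlation. In camera with the region term excitatory neuron genes passed the other way, upward with an adjusted p of 0.0373, and hypothalamus stayed upward with an adjusted p of 0.0370, while both had an adjusted p of 0.749 with an estimated correlation in that fit. Cerebellum, choroid plexus, hindbrain and immediate early genes did not pass there, with an adjusted p in camera of 0.801, 0.600, 0.706 and 0.0905. The cerebellum and hindbrain lists had helped form the library classes, so their loss was no independent test. TG females held 2 libraries with hindbrain markers and the 1 with cerebellum markers, and WT females 1 with hindbrain markers and 1 with cortex markers.

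In males, Gm15446 alone passed the threshold between TG and WT, rising by a log2 value of 5.49 ± 0.33 with an adjusted p of 5.65e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 named genes with the smallest p, Mcm6, Pcdhb3 and Aldh7a1, did not pass. Mcm6 had a difference of -2.41 ± 0.39, Pcdhb3 one of 1.10 ± 0.20 and Aldh7a1 one of -0.69 ± 0.12, each with an adjusted p of 0.248 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In males 46 genes passed with the region term, and DESeq2 called 41.

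In camera 14 lists passed in males, 3 upward and 11 downward, and 0 did so with an estimated correlation or in fry. Myelin genes were negative in 30 of 30 members with a median of -1.29, cholesterol synthesis genes in 23 of 23 with a median of -0.51, and hindbrain genes in 20 of 20 with a median of -7.41. Their adjusted p in camera was 9.41e-10, 9.41e-10 and 9.10e-04, and the adjusted p was 0.853 for each with an estimated correlation. Interferon response genes were positive in 32 of 34 members with a median of 0.54, an adjusted p in camera of 9.12e-06 and an adjusted p of 0.853 with an estimated correlation. WT males held 1 library with hindbrain markers and TG males none. With the region term the medians of the myelin and cholesterol lists in males were -0.36 and -0.30, with adjusted p in camera of 1.08e-05 and 5.66e-15, and an adjusted p of 0.948 and 0.302 with an estimated correlation. In fry with that term the cholesterol list alone passed, downward with an adjusted p of 0.0264, and hindbrain genes, which had helped form the library classes, did not pass in camera, with an adjusted p of 0.863.

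The genotype-by-sex interaction called 0 genes in edgeR's quasi-likelihood test, where 698 genes had an unadjusted p under 0.05, 0 genes in limma-voom and 5 in DESeq2. The 3 named genes with the smallest p, which did not pass, were Eppk1, a cytoskeletal linker, Tmem267 and Nectin2, a cell adhesion protein. Tmem267 lay at 25.8 ± 7.60 CPM in TG females and 7.68 ± 2.60 CPM in WT females, and at 30.2 ± 9.49 and 30.98 ± 6.20 CPM in TG and WT males. Its log2 interaction was 1.78 ± 0.43, that of Eppk1 3.30 ± 0.77 and that of Nectin2 0.90 ± 0.23, each with an adjusted p of 0.724 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In camera 24 lists passed for the interaction, 19 upward and 5 downward, led by the myelin list with a median of 1.85 and an adjusted p of 1.45e-09. With an estimated correlation 0 passed, with an adjusted p of 0.452 for the myelin list, and the libraries with hindbrain markers were 2 of 4 in TG females, 1 of 4 in WT females, 1 of 4 in WT males and none in TG males.

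Females and males differed in 7 genes, which checks the sex labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay at 75.1 to 112, 21.6 to 60.5, 25.6 to 51.1 and 10.9 to 16.4 CPM in the 7 male libraries and at no more than 0.109, 0.0604, 0.0568 and 0 CPM in the 8 female ones. Xist, the RNA that silences 1 X chromosome in females, lay at 1017 to 2913 CPM in females and 0.573 to 6.59 CPM in males. Eif2s3x and Gm2223, both on the X chromosome, were higher in females by log2 values of 0.65 ± 0.08 and 0.62 ± 0.08. Both had an adjusted p of 0.00497 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ddx3x, Kdm6a, Kdm5c, Pbdc1 and Utp14a, other X genes read for escape from silencing, did not pass, with differences of 0.48 ± 0.08, 0.69 ± 0.16, 0.37 ± 0.13, 0.16 ± 0.11 and -0.08 ± 0.09.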

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

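The tests of region content as a source of the region markers, those of chromosome positions outside the protocadherin sum and all fits with the region term were chosen after the results were seen.

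Libraries of the same group differed in brain region markers, and the 4 classes explained 98.5% of the first principal component. Depth as the whole source is argued against, since after thinning all libraries to equal totals the classes still explained 98.5% of it. Without any of the 92 genes of the region lists the classes explained 98.3% of the leading component, above the 47.1% that 95% of 10000 shuffles stayed under. The classes thus extend to other genes. Since they were formed from the same libraries, this cannot tell region content from another library-wide difference. Hoxa5 lay at no more than 0.0921 CPM in the remaining libraries and those with cortex markers, under the limit that 3 counts allow. Gabra6 lay at no more than 0.181 CPM in the remaining libraries and 0.0617 CPM in those with cortex markers. These values argue against every sample being a whole hemisphere with brainstem and cerebellum. That samples held different regions among hindbrain, cerebellum, cortex and olfactory bulb is a hypothesis that the labels do not address.

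Without the region term, the 16 called genes with a position lay in 7 loci, and with it 81 lay in 43 loci. Most of these calls lay on chromosomes 1, 17 and 18, and segments of another strain's DNA carried in the TG line are a candidate explanation. With the region term, 38 pairs of called loci lay within 20 Mb of each other, against a median of 15 in draws of as many genes as loci (permutation p 1e-04, the smallest that 10000 draws can give). Outside families, meaning without protocadherins, predicted genes, pseudogenes and IDs without a symbol, 35 pairs remained (permutation p 3e-04). Reads shared among the genes removed therefore cannot be the whole cause there. Members of other multi-copy families were not removed, so reads shared within those were not tested. This statistic was the third tried. Counting loci with a neighbour against draws of as many genes as called gave permutation p 1 for all calls and 0.32 outside families. Counting pairs against those draws gave 0.46 and 2e-04, so the result for all calls rests on the choice of draws. Against the final draws, counting loci with a neighbour gave permutation p 0.025 for all calls and 0.028 outside families. Simulated stretches were found in 17 of 20 sets by pairs and in 3 by loci with a neighbour, both against the final draws. The earlier draws were not simulated, so the simulation cannot decide between the draws. Without the region term the 7 loci gave p 0.04 and the 5 outside families p 0.16 (0.48 and 0.26 against draws of as many genes), but all 19 calls stayed with that term, which argues against region content, and in the fit with the term 15.6% of the uncalled genes within 5 Mb of these loci had an unadjusted p under 0.05 against 7.72% elsewhere. The summed γ-protocadherin count rose by a log2 value of 0.21 ± 0.05 with the region term (p 6.21e-04; 0.12 ± 0.18, p 0.512 without it), which argues against a pure exchange of reads between members, while a partial exchange, shared regulation of neighbouring genes and the transgene itself stay open and untested.

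Splits of the samples at random gave results as large as follows. The splits treat the samples as independent of each other. For TG versus WT, 3 of 100 splits, the real one included, called 19 genes or more, with up to 3104 in another split. With the region term only the real split of 100 reached its 85 genes, the highest other having 4. Both shares argue against chance without excluding it. None of the shares given here was adjusted for the number of results tested. For females 2 of 35 splits reached 8 genes, with up to 2799 in another, so chance is not excluded. For males 1 of 35 reached the 1 gene called, the highest other having 0, and for sex 3 of 100 reached 7 genes, the highest other having 1759. These shares also argue against chance without excluding it. For the interaction all 100 splits reached 0 genes, the highest other having 3105. The largest counts, many times the real one, point to a structure of the samples, since the split with the most genes put all libraries with hindbrain markers on 1 side for TG versus WT, for females and for sex, though not for the interaction. For lists, 69 of 100 splits reached the 13 past the threshold (highest other 26), 81 of 100 the 8 with the region term (24), 10 of 35 the 20 in females (23), 26 of 35 the 14 in males (27) and 14 of 100 the 24 of the interaction (28), so chance is not excluded for any of these counts. By list, a p as small was met in 16 splits of 100 for interferon response, 6 for antigen presentation, 9 for cholesterol synthesis and 5 for glucocorticoid response.

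A library far from the other 3 of its group was met in 51 of 254 groups of 4 tested, where chance gives about 1 in 20 for genes not chosen by their values. The genes tested were the named ones, which include the library markers chosen after their values were seen, so this share does not measure an excess. The groups are also not independent because the same libraries recur. WT male 3, with hindbrain markers, stood apart in CPM for Sncg (70.4), Car2 (351), Hapln2 (216), B2m (75.6), Cd14 (5.36), Ly6g6f (4.13), Cd59a (76.9), Klk6 (32.3), Anln (145), Hoxa5 (69.3), Slc6a5 (81.6), Mbp (11960) and, on the low side, Nav1 (208). WT female 3, also with hindbrain markers, stood apart in CPM for Sncg (32.9), Car2 (325), Hapln2 (227), Cd14 (6.17), Bhlhe41 (54.3), Ly6g6f (5.11), Klk6 (39.3), Anln (174), Hoxa5 (112), Slc6a5 (73.5), Mbp (13230), Gabra6 (1.19) and Cbln3 (5.50). TG female 3, with cerebellum markers, stood apart in CPM for Gabra6 (701), Cbln3 (2063), Gdf10 (251), Ddx3x (661), Ermard (33.8) and Ide (53.3), and was low for Rps2 (207). TG female 2, the 1 TG female among the remaining 7 libraries, stood apart in CPM for Lgals3bp (22.4), Foxp2 (36.2), Fezf2 (3.04), Gng7 (322), H2-Q7 (18.1), H2-Q6 (11.6), Gpr55 (1.62), Omp (55.3) and Th (89.5). WT female 2, with cortex markers, stood apart in CPM for Pcdhga8 (21.5), Tnnt2 (7.05), Fezf2 (78.9) and Neurod6 (131), and was low for Irf9 (16.3). WT male 1 was high for Aldh7a1 (44.7 CPM), WT male 2 for Pcdha8 (2.07 CPM), and WT male 4 was low for Pcdhb8 (5.12 CPM) and Aim2 (1.11 CPM).

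The genotype-by-sex interaction passed in camera for 24 gene lists, and for 0 with an estimated correlation. TG females 1 and 4 but no TG male had hindbrain markers, and TG female 3 alone had cerebellum markers, so region content is not separated from sex here. With the region term the hindbrain, cerebellum and choroid plexus lists did not pass for the interaction, with an adjusted p in camera of 0.989, 0.604 and 0.453. The hindbrain and cerebellum lists had helped form the classes of that term, so their loss cannot decide whether region content was the source. Lists with a higher difference of TG over WT in females, given as the median log2 interaction, were hindbrain (8.33), hypothalamus (3.38), choroid plexus (3.12), cerebellum (2.38), myelin (1.85), dopaminergic neuron (1.72) and blood (1.38). They also included disease-associated microglia (0.71), mural cell (0.57), cholesterol synthesis (0.56), complement (0.52), glucocorticoid response (0.52), antigen presentation (0.46), astrocyte (0.45) and reactive astrocyte (0.34). Smaller medians were those of endothelium (0.24), lysosome (0.24), ribosomal protein (0.24) and oxidative phosphorylation (0.22). Lists with a lower difference of TG over WT in females were immediate early (-1.77), excitatory neuron (-1.40), inhibitory neuron (-0.53), circadian clock (-0.33) and synaptic vesicle (-0.16). The interaction passed for 10 lists with the region term, 8 of them among these 24, and 2 of the 8 passed the other way: excitatory neuron upward and astrocyte downward, with an adjusted p in camera of 0.034 and 0.038. With an estimated correlation 0 lists passed for the interaction with that term, the smallest adjusted p being 0.977.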

How the results depend on the processing

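The region term and the settings without 5 libraries were chosen after seeing the data, and the other settings were planned. Where a count moved, the cause was not tested. Of 241 alternatives of the counts, 186 gave a result within 1.5 times. List by list, some calls passed the other way in camera: with the region term excitatory neuron genes upward and astrocyte genes downward, in females (adjusted p 0.0373 and 0.0124) and for the interaction (0.034 and 0.038), excitatory neuron genes for the interaction also with that term and without the 5 libraries named below (0.0164), and with 1 surrogate variable myelin genes downward in females (1.17e-06). For TG versus WT (19 genes), DESeq2 called 40, 1 surrogate variable 32, the region term 85, the fit without the 5 libraries with hindbrain or cerebellum markers 7, and both together 41. For females (8 genes) the counts were 4 with no filter, 20 in DESeq2, 5 in limma-voom, 1 in the 8 females alone, 21 with the region term and 1 without the 5 libraries. For males (1 gene) they were 41 in DESeq2, 6 with 1 surrogate variable, 46 with the region term and 23 with the region term and without the 5 libraries. DESeq2 called 5 genes for the interaction (0), and the region term 12 for sex (7). With estimated correlation and in fry 0 lists passed in each of the 4 comparisons without the region term, and with it 0 passed with estimated correlation (smallest adjusted p 0.749 in females, 0.977 for the interaction). With the region term 8, 12, 6 and 10 lists passed for both sexes (13), females (20), males (14) and the interaction (24). With 1 surrogate variable 11, 8 and 8 passed for females, males and the interaction, without the 5 libraries 13, 9 and 14, and with both changes 8 for males and 12 for the interaction.

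With 1 library left out, counts ran from 14 to 21 genes for TG versus WT, 1 to 7 in females, 1 to 2 in males, 0 to 0 for the interaction and 7 to 7 for sex. Counts of lists ran from 10 to 22, 13 to 22, 7 to 20 and 17 to 25. The lowest count in females was that without TG female 1 or TG female 4, and the highest of lists for both sexes that without WT male 3, all with hindbrain markers. Of 12 named called genes, 9 were called in all planned settings that kept every library, 9 with any 1 library left out, 12 with the region term, 4 without the 5 libraries and 11 with both changes, with 0 sign changes. Of 75 named genes not called, 21 changed sign in at least 1 setting. The replicate numbers did not pair the samples: 7 of 21 same-number pairs had a deviation correlation over 0.1, with a range of -0.63 to 0.92, and with the replicate block 16 genes were called for TG versus WT and 4 in females. At these depths and this spread, 16% of simulated 1.5-fold changes between TG and WT were recovered.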

Other observations

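All values here come from planned lists and tests, except the fits with the region term, which were chosen after seeing the data.

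Within females, the region term left striatal projection neuron genes higher in TG, with 20 of 20 members positive and a median log2 difference of 0.67, and within males lower, with 0 of 20 positive and a median of -0.95. The adjusted p in camera was 2.18e-06 and 1.91e-04, and the adjusted p was 0.749 and 0.948 with an estimated correlation. These neurons of the basal ganglia are among those lost in multiple system atrophy. The interaction passed in camera with this term, with an adjusted p of 2.72e-09 and an adjusted p of 0.977 with an estimated correlation, while without it the list had an adjusted p of 0.382. The classes hold few libraries per group, and within the 7 remaining libraries the mean log2 CPM of this list ran from 3.79 to 6.27. Libraries of a class were thus not alike for this list, and whether their region content differed was not tested. WT male 1 (6.27) and TG female 2 (6.21) were the highest, in the directions of the male and female results. Without the region term the list had an adjusted p in camera of 0.786 in males when WT male 1 was left out, and passed downward in females when TG female 2 was left out (1.91e-04).

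Ribosomal protein genes lay higher in TG females with and without the region term, with 35 and 34 of 36 members positive and medians of 0.09 and 0.18. The adjusted p in camera was 2.18e-06 and 2.79e-06, and the adjusted p was 0.749 and 0.618 with an estimated correlation. In males the list passed downward without the term, with a median of -0.08 and an adjusted p in camera of 0.0353 and of 0.853 with an estimated correlation, and did not pass with it, with an adjusted p of 0.622. These genes averaged a log2 CPM of 6.48 with hindbrain markers and 6.09 with cortex markers, and TG females held 2 libraries with hindbrain markers, so region content is not excluded for the result without the term. The term does not cover differences between libraries of 1 class, so region content is not excluded for the result with it either.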
